A study of Mus musculus with 4 samples.

How the data were processed

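RNA was extracted from freshly sorted mouse HSCs with a Qiagen RNeasy Micro kit and made into libraries with a TruSeq RNA kit after polyA selection, and the libraries were sequenced on a HiSeq 2000, per the labels. This kit as named does not mark strand, so reads of overlapping features on opposite strands cannot be told apart. Counts are whole numbers of reads per feature that the authors deposited for each library. The aligner, the counting tool and the annotation are not given in the sources used here. The build mm9 and the tool DESeq are named per the submitters' processing notes, with no version or role. Spans in the table equal end - start + 1 for 8786 gene symbols with the same span in GENCODE vM21 and end - start for 541, so coordinates were read as 1-based, and no coordinates were taken from that annotation.

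A length-scaled signal was also deposited by the authors for each library under an FPKM heading. Its ratio to the count was the same in every library for 20187 features, to within a relative difference of 3.7e-14, although library totals differ, so it equals the count per kb of exon divided by a constant of 50 where the library's own depth would stand. It was used only to obtain exon lengths. The authors' deposited log2 fold change was found from the values to be knockout over wild type after scaling: it differed from log2 of the knockout mean over the size-factor-normalised wild-type mean by 0.399 (SD 0.012 over 14626 features). For features of low counts it follows the same ratio with about 1.22 normalised counts added to both means, with an SD of 0.056 about that formula, so it understates their folds. The p-value column deposited by the authors is read here as adjusted, since 6641 of 8375 well-counted features share their value with another feature and 1549 values equal 1. The deposited direction column marks each feature with a value under 0.05 by its sign, for all 34315 features.

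Of the 30 columns in the table, 8 hold per-library values with no matching sample here and were not used. Wild-type counts were divided by median-of-ratios size factors of 0.951, 0.955, 1.048 and 1.065, and the authors' knockout mean was placed on that scale with the offset above. The 4 wild-type libraries are technical replicates of 1 biological replicate per the labels, while the series design speaks of duplicates. Libraries that differed by little more than counting noise were averaged and counted as 1 sample, which gave libraries 1 and 2 and libraries 3 and 4. Agreement was tested with a chi-square test of homogeneity per feature on counts, expected from library totals, over features with at least 20 reads. At the depths of 40709659 to 47408552 counts, 0 reads in a library allows up to 0.0737 CPM, taking 3 counts as the floor. A gene with 0 reads in the knockout arm is given a bound against 3 counts over the arm's 4 libraries, and a gene with 1 to 3 reads in an arm is given an exact Poisson 95% interval of the ratio. Both cover counting error only.

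No test between genotypes was run, and calls are those of the authors' deposited table at an adjusted p under 0.05. The 22 gene lists, the choice of named genes and most alternative settings were fixed before the data were examined, and the others were added later. The lists are stem cell identity, genes linked to Dnmt3a loss, DNA methylation machinery, Polycomb and Trithorax, Hox clusters, other developmental transcription factors, erythroid, megakaryocyte, myeloid, lymphoid, mast cell and basophil, and stromal and endothelial markers, cell cycle, cell cycle inhibitors and p53 targets, immediate early, interferon-stimulated, imprinted, leukaemia-associated, ribosomal, mitochondrial, housekeeping, and adhesion and niche genes. List members with no match by name included Hbb-bs, Hbb-bt, Ahsp and Ifi27, and some items are not reported here. A member was measured if the mean of both arms was at least 10 normalised counts. Each median was set beside 10000 random lists of the same size drawn within 20 bins of mean expression from 12548 features with gene symbols, as a description of these libraries and not a test. For some lists the number of members called is also set beside that in the same random lists. Counts adjusted over the list alone are lower bounds, since only adjusted values were at hand: the largest unadjusted p that each allows was adjusted again by the Benjamini-Hochberg method.

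Named genes were the 12 largest rises and 12 largest falls among called genes with a symbol and a mean of at least 50, up to 4 called members per list with the largest changes, all members of the methylation machinery, and, in wild type, the 15 highest genes and the stem cell list, with examples in the text. Other genes named in the text were chosen after their values were seen, which holds for Jun, the granule genes, Lyz2, Hoxa9, Gata1, the globins, Peg10, Plagl1, Cdkn2c and the genes of the added sets in the closing section. Features overlapping another feature with at least 10% of their mean number 291 among the 1490 called.

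The statistics were tested on simulated data. With 200 of 19310 features changed 4-fold in 2 of 4 simulated libraries, the chi-square test recovered 200 and called 12 others. Of 100 unchanged lists of 30 genes, 93% lay inside the central 95% of random lists drawn from 12548 features, and all 10 lists of 20 genes shifted by 1 on the log2 scale lay above it. Alternatives changed the p threshold, the minimum fold or mean, the scaling, the matching of random lists, and the libraries used, with 2000 random lists for each list alternative. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.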

Results

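Messenger RNA was sequenced from haematopoietic stem cells (HSCs), the bone marrow cells that renew themselves and give rise to every blood lineage. The cells were sorted from C57BL/6 mice as side population (SP) cells, which pump out a DNA-binding dye, that also had the KSL-CD150+ surface phenotype. The series sets wild-type HSCs beside HSCs labelled as lacking Dnmt3a, a de novo DNA methyltransferase. The samples are 4 wild-type libraries, which the labels describe as technical replicates of biological replicate 1, with read counts for 34315 features in mm9 coordinates. Library totals were 40709659, 40798800, 47408552 and 47365062 counts for replicates 1 to 4. The arm labelled knockout enters only through the authors' deposited table, as a mean count per feature, a log2 fold change over wild type and a p-value.

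In wild-type HSCs the genes with the highest normalised read counts included the translation factors Eef1a1 and Eef2, mitochondrial cytochrome b (Cytb), the adhesion receptor Gpr56 and the chaperone Hsp90ab1. These counts were not divided by transcript length, so they do not rank numbers of transcripts. Among known stem cell genes, the cytokine receptor Kit averaged 56138 normalised counts in libraries 1 and 2 and 65243 in libraries 3 and 4, and the transcription factor Hlf averaged 28976 and 40042. Cd34, a surface protein used to subdivide HSCs, averaged 14026 and 13123, the transcription factor Meis1 16249 and 16086, and the endothelial protein C receptor Procr 2964 and 4894. Markers of differentiated cells took small shares of the counts. Megakaryocyte markers, several of which HSCs also express, held 0.394% of all counts over the 4 libraries. Erythroid markers held 0.193%, mast cell and basophil markers 0.192%, myeloid markers 0.139%, stromal and endothelial markers 0.0682% and lymphoid markers 0.0308%. The mast cell list includes the stem cell genes Kit and Gata2, so its share is not one of mast cells alone. In libraries 1 and 2 the myeloid share, at 0.199% and 0.195%, exceeded the erythroid share, at 0.180% and 0.184%. The exact binomial 95% interval was 0.1388% to 0.1399% for the myeloid share, and such intervals cover counting error only, since PCR copies are not independent molecules.

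The 4 libraries fell into 2 closely matching pairs. Immediate early genes, which are switched on within minutes by signals and stress, differed widely: Fos stood at 854 normalised counts in libraries 1 and 2 and at 49960 in libraries 3 and 4, Egr1 at 2135 and 70737, Jun at 1946 and 34555, and Klf2 at 51.4 and 4082. The median log2 difference over the 32 measured immediate early genes was 3.35, against a central 95% of -0.08 to 0.22 in random lists matched on expression. Neutrophil granule genes went the other way, with Ngp at 9185 and 1096, S100a8 at 7708 and 1159 and Ltf at 6740 and 811, so that myeloid markers held 0.199% and 0.195% of the counts in libraries 1 and 2 and 0.0891% and 0.0906% in libraries 3 and 4. Lyz2, expressed by macrophages and neutrophils, was at 9682 and 11560. Jun, Lyz2 and the granule genes are named here after their values were seen.

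A chi-square test of homogeneity per feature gave a median of 7.58 and a mean of 78.0 for chi-square per degree of freedom over the 4 libraries, where simulated counting noise gave 0.808 and 1.01. Libraries 1 and 2 alone gave a median of 0.762 and a mean of 2.03, and libraries 3 and 4 gave 0.681 and 1.87, where counting noise gave 0.46 and 1.01 for a pair. The lowest median between a library of the first pair and a library of the second was 12. Each pair therefore differed by little more than counting noise and is given as 1 averaged value below. Of 13161 features with a mean of at least 100, 869 (6.6%) were at least 2-fold apart between the pairs, 233 of them higher and 636 lower in libraries 3 and 4, and no test of this difference was run because the pairs are not labelled groups.

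**Figure D1:**
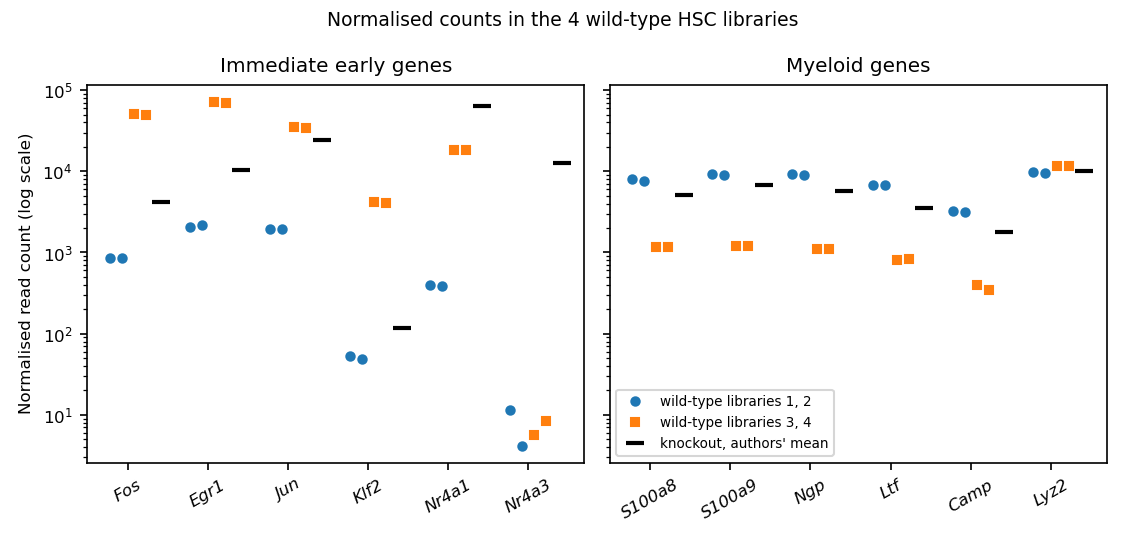
Normalised read counts on a log axis for 6 immediate early genes and 6 myeloid genes, with a point for each of the 4 wild-type libraries and a bar for the authors' knockout mean on the same scale. For Fos, libraries 1 and 2 sit near 854 and libraries 3 and 4 near 49960, whereas Lyz2 is at 9682 and 11560.

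Dnmt3a itself was examined first (chromosome 12, 3806980 to 3914443, mm9). It averaged 8399 normalised counts in libraries 1 and 2, 5304 in libraries 3 and 4 and 8425 in the arm labelled knockout. Its log2 fold change in the authors' deposited table was 0.30, with an adjusted p of 0.952. Which part of the gene was deleted is not given in the sources used here, and a count over the whole gene does not check the label if transcripts without that part are still made. The 18 measured genes of the DNA methylation machinery included none called in either direction, and their median log2 fold change in the authors' deposited table was -0.15, inside the random range of -0.26 to 0.63, although against libraries 1 and 2 alone it was -0.23 and below its range. Random lists had a mean of only 0.44 members called higher and 0.12 lower, so the lack of calls says little. The maintenance methyltransferase Dnmt1 had a log2 fold change of -1.18 (adjusted p 0.536), its partner Uhrf1 -1.95 (0.168), the helicase Hells -2.02 (0.145), the other de novo enzyme Dnmt3b -0.35 (0.938) and the dioxygenase Tet2 1.77 (0.237) in the authors' deposited table, with Tet2 at 2796 and 789 in the wild-type pairs.

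The comparison of the arm labelled knockout with wild type asks which transcripts differ between them. In the arm labelled knockout, 685 features rose and 805 fell at an adjusted p under 0.05 in the authors' deposited table, out of 21778 tested. Of these, 473 and 525 carry a gene symbol. The others have only locus numbers or predicted-gene, clone, accession-like, microRNA or snoRNA names, which were not counted as symbols here. The smallest called rise was 5.69-fold, and 6673 tested features that were at least 2-fold apart were not called. The knockout mean lay above both wild-type pairs for all 685 features called higher and below both for 801 of the 805 called lower. The exceptions were Fos, Klf2 and the antisense features that overlap them, HAG_008909 and HAG_040063, whose knockout means lay between the pairs. The called rises had to lie above both pairs, since each was at least 5.69-fold over the wild-type mean. Neither pair can exceed that mean by more than 2-fold. The knockout value is a mean over 4 libraries, and the spread between them was not examined, so single knockout libraries may lie elsewhere.

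The largest rise was that of Nr4a3, an orphan nuclear receptor (chromosome 4, 48064120 to 48096224), from 7.88 and 7.09 normalised counts in the wild-type pairs to 12622, a 1481-fold change with an adjusted p of 1.55e-13 in the authors' deposited table. The ephrin ligand Efna3 rose 773-fold, the galectin Lgals7 311-fold, the inhibitory receptor Pdcd1 277-fold and the corepressor Hr 221-fold according to the authors' deposited table. Nipal1 rose 170-fold, the kinase inhibitor Camk2n1 148.5-fold, the receptor partner Ramp3 141-fold and the cell cycle inhibitor Cdkn2b 127-fold in the same comparison of the authors' deposited table. The wild-type pairs differed for Camk2n1, at 35.2 and 86.1 normalised counts, and for Ramp3, at 0.523 and 3.31. Cib3 rose from 2 wild-type reads to 730, a ratio with a counting interval of 134 to 3990. Itga3, an integrin chain, reached 51453 normalised counts from 411 and 575, and Pmepa1, a feedback inhibitor of TGF-beta signalling, reached 14090 from 115 and 166, which the authors' deposited table gives as 104-fold and 99.2-fold.

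Among the named genes, the largest falls were those of Ndn and Meg3, both imprinted. The median of the imprinted list lay inside its random range, but the number of its members called lower lay above that of most random lists. Ndn, paternally expressed and linked to stem cell quiescence (chromosome 7, 69493163 to 69494813), went from 1266 and 2244 normalised counts to 1 read in the knockout arm, a ratio with a counting interval of 956 to 210000. It shares its position with the antisense feature HAG_037550, which reads without strand cannot separate from it. The maternally expressed noncoding RNA Meg3 (chromosome 12, 110779206 to 110809939) also fell to 1 read, a ratio of 612 to 135000, but the wild-type pairs themselves stood at 2119 and 129, and against the lower pair the ratio is 70.3 to 15500. The Snrpn and Snurf locus had 0 reads and was at least 217-fold lower. Tmem47 was at least 364-fold lower, Mpped2 at least 288-fold, the desmosomal cadherin Dsc2 at least 216-fold, Rnf17 at least 201-fold and Luzp2 at least 198-fold, each with 0 reads in the knockout arm. Against libraries 1 and 2 alone, the lower pair, the bounds are 224-fold for Tmem47 and 105-fold for Luzp2. Dcaf12l1 fell 317-fold, the hepatocyte nuclear factor Hnf4a 250-fold and Zfp951 199-fold in the authors' deposited table. Rps4y2 fell 156-fold in the authors' deposited table, but it lies within Tmtc1 and resembles Rps4x, so its count is uncertain.

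**Figure D2:**
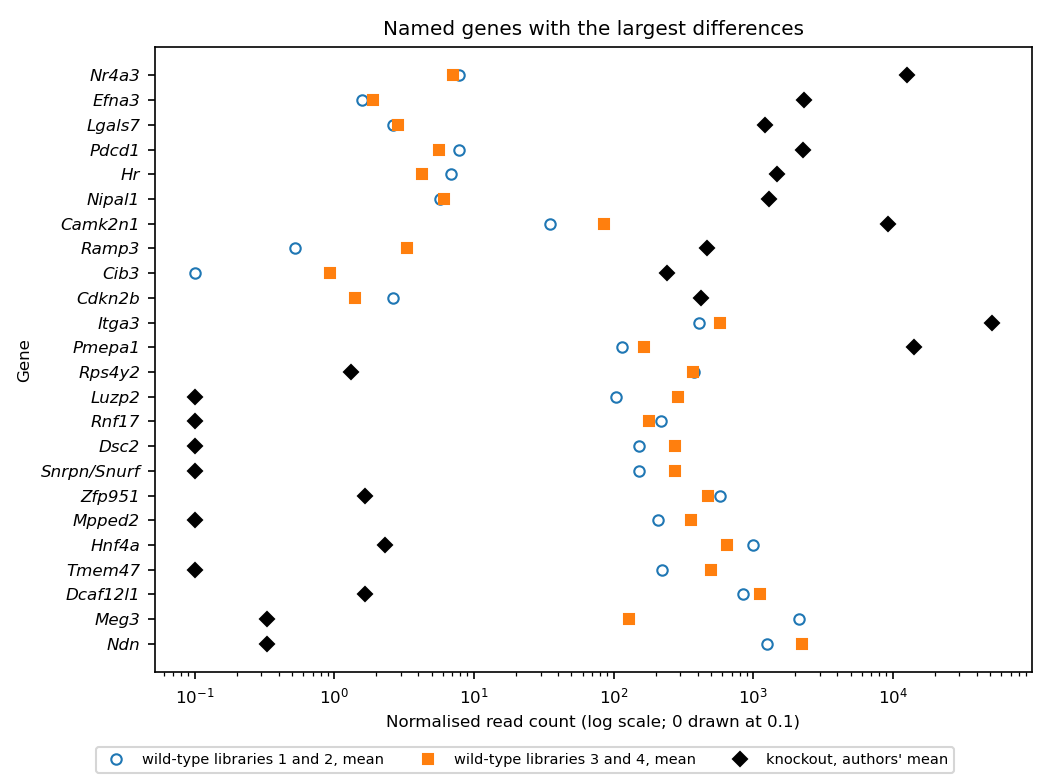
Normalised read counts on a log axis for the 12 named genes with the largest rises and the 12 with the largest falls, with the mean of wild-type libraries 1 and 2, the mean of libraries 3 and 4 and the authors' knockout mean. Nr4a3 lies at 7.88 and 7.09 in wild type and 12622 in the knockout arm, and Meg3 lies at 2119 and 129 in wild type.

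Several genes of embryonic patterning rose in the knockout arm. Of 117 developmental transcription factors and related regulators other than Hox genes, 18 were measured, of which 9 rose and 2 fell, or at least 10 and 2 adjusted over the list alone, and their median log2 fold change in the authors' deposited table was 2.39 against a random range of -1.16 to 0.45. The median was 1.41 with no minimum level, which matters because genes near silence in wild type pass the minimum through the knockout arm alone. Six2 rose from 1 wild-type read, a ratio of 60.4 to 13300, Sall3 from 2 reads, a ratio of 20.2 to 602, and Foxa1 rose 21.6-fold in the authors' deposited table, from 0 and 2.37 normalised counts in the wild-type pairs, while the LIM-homeodomain factor Isl1 fell to 0 reads and was at least 51.3-fold lower. Most of these genes were near silent in wild type, where the list's median level was 14.8 normalised counts. Among 20 measured Hox genes of 39, 5 rose and none fell, at least 8 and 0 adjusted over the list alone, with a median of 1.25 in the authors' deposited table against -0.84 to 0.32 for random lists, and of 0.99 with no minimum level. The Hoxb cluster supplied 4 of the 5: all 9 measured Hoxb genes had a positive log2 fold change, with Hoxb9 rising 22.9-fold, Hoxb1 31.1-fold and Hoxb8 7.28-fold in the authors' deposited table, although Hoxb1 overlaps the antisense feature HAG_007127. Hoxd13 rose from 1 wild-type read, a ratio of 16.6 to 3660. Like Hoxb1, which had 10 wild-type reads, it passed the minimum through the knockout arm alone. None of the 9 measured Hoxa genes was called, and Hoxa9, the most studied of them in leukaemia, had a log2 fold change of 0.99 and an adjusted p of 0.655 in the authors' deposited table.

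Many erythroid genes and some megakaryocyte genes fell. Of 24 measured erythroid genes, 11 fell and 0 rose, at least 15 adjusted over the list alone, and the median log2 fold change in the authors' deposited table was -2.54 against -0.77 to 0.40 for random lists. Rhag fell 106.5-fold, carbonic anhydrase Car1 60.5-fold, Ermap 52.9-fold and the master regulator Gata1 31.5-fold in the authors' deposited table, and Cldn13, with 0 reads, was at least 102-fold lower. The globin loci were not called: Hba-a1 with Hba-a2 had a log2 fold change of -0.75 and Hbb-b1 with Hbb-b2 -0.86 in the authors' deposited table. Of 20 megakaryocyte genes, 5 fell and 0 rose, at least 6 adjusted over the list alone, while 8 had a positive log2 fold change, with a median of -0.83 in the authors' deposited table against -0.34 to 0.60. The platelet glycoprotein Gp5 fell 32.4-fold, the chemokine Pf4 9.57-fold and F2rl2 9.99-fold in the authors' deposited table, although F2rl2 overlaps Iqgap2. The clotting factor gene Vwf was not called, at a ratio of 2.82 and an adjusted p of 0.364 in the authors' deposited table.

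Several lymphoid and mast cell genes fell as well, and few myeloid genes were called. Of 21 lymphoid genes, 8 fell and 1 rose, the same numbers at least adjusted over the list alone, with a median of -1.82 in the authors' deposited table against -1.0 to 0.39 for random lists. The interleukin receptor Il7r had 0 reads and was at least 68.1-fold lower, or 26.5-fold against the lower wild-type pair, the recombinase Rag1 fell to 1 read, a ratio of 13.3 to 2940, or 6.96 to 1530 against the lower pair, and Ccr9 fell 13.3-fold in the authors' deposited table, from 17.3 and 129 normalised counts in the wild-type pairs to 4.28. Of 10 mast cell and basophil genes, 4 fell and 0 rose, at least 5 and 1 adjusted over the list alone, with a median of -2.28 in the authors' deposited table against -1.17 to 0.74. The mast cell median was -1.45 against libraries 1 and 2 alone and -2.68 against libraries 3 and 4 alone. Fcer1a, the IgE receptor chain, fell 65.0-fold, Cpa3 8.003-fold and Prss34 32.6-fold in the authors' deposited table, with Prss34 at 28.9 and 454 in the wild-type pairs. Among 32 myeloid genes, Cd14 rose 39.8-fold and the macrophage gene Emr1 fell 6.94-fold in the authors' deposited table, at least 1 and 1 adjusted over the list alone, and the list median of -0.05 lay inside -0.55 to 0.36. In the wild-type pairs Cd14 was at 32.5 and 81.4 normalised counts and Emr1 at 161 and 77.2, with knockout means of 2324 and 15.8. Against libraries 1 and 2 alone the myeloid median was -0.59, and against libraries 3 and 4 alone it was 0.50.

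A number of cell cycle genes fell, and inhibitors of the cycle changed in both directions. Of 52 measured cell cycle genes, 15 fell and 0 rose, at least 24 adjusted over the list alone, with a median log2 fold change of -1.82 in the authors' deposited table against -0.19 to 0.34 for random lists. The mitotic cyclin Ccnb1 fell 20.6-fold, from 2127 and 1937 normalised counts to 96.9, and Ube2c fell 15.6-fold, Ccna2 15.4-fold and Ccnb2 13.4-fold in the authors' deposited table, with Ccna2 sharing part of its position with Exosc9. Of 25 cell cycle inhibitors and p53 target genes, 4 rose and 1 fell, at least 7 and 1 adjusted over the list alone, with a median of 1.08 in the authors' deposited table against -0.42 to 0.46. Besides Cdkn2b, the inhibitor Cdkn1a rose 14.2-fold, the apoptosis gene Perp 8.90-fold and Gadd45b 8.19-fold in the authors' deposited table, with Cdkn1a at 185 and 872, Perp at 135 and 297 and Gadd45b at 175 and 449 in the wild-type pairs. The member that fell is also an inhibitor of the cycle, Cdkn2c, by 6.42-fold with an adjusted p of 0.0331 in the authors' deposited table, and is named after its values were seen.

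Immediate early genes moved in both directions, in the list that also separated the wild-type pairs by 3.35. Of 32 measured members, 10 rose and 3 fell, at least 13 and 3 adjusted over the list alone, with a median of 1.46 in the authors' deposited table against -0.09 to 0.57 for random lists. Nr4a2 rose 66.3-fold beside Nr4a3, and the heat shock gene Hspa1a rose 25.6-fold in the authors' deposited table, although its near-identical copy Hspa1b can share its reads and Hspa1a stood at 1.05 and 18.9 in the wild-type pairs. Klf2 fell 17.4-fold in the authors' deposited table, yet its knockout mean of 117 was above the 51.4 of libraries 1 and 2. Fos fell 6.10-fold and Myc 8.08-fold in the authors' deposited table, and the Fos mean of 4173 likewise lay above the 854 of libraries 1 and 2. The 10 genes called higher were at least 2-fold above both pairs, which the size of a called rise over the wild-type mean requires. Falls are not bound in this way, and 1 of the 3 called lower, Myc, was at least 2-fold below both.

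Adhesion and niche signalling genes rose more often than they fell. Of 39 measured, 9 rose and 1 fell, at least 10 and 1 adjusted over the list alone, with a median of 0.66 in the authors' deposited table against -0.16 to 0.50. The Notch ligands Jag1 and Dll1 rose 18.2-fold and 12.8-fold and the Kit ligand gene Kitl 10.6-fold in the authors' deposited table, while N-cadherin, Cdh2, had 0 reads and was at least 22.3-fold lower. Kitl was at 41.4 and 86.6 normalised counts in the wild-type pairs and 690 in the knockout arm.

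Most stem cell genes were not called. Of the 44 genes of stem cell identity, Neo1 rose 18.4-fold while Ndn and Cd34 fell, Cd34 by 26.4-fold, in the authors' deposited table, at least 2 and 2 adjusted over the list alone, and the median of 0.18 lay inside 0.02 to 0.54. Procr had a log2 fold change of 2.44 (adjusted p 0.0589), Slamf1, which encodes CD150, 1.11 (0.579) and Hlf -1.86 (0.201) in the authors' deposited table. Among 19 genes that earlier work links to Dnmt3a loss, a list that may draw on studies of these cells, Nr4a2 and Cdkn1a rose and Fos fell, at least 2 and 1 adjusted over the list alone, with a median of 0.42 in the authors' deposited table inside -0.24 to 0.66. Against libraries 1 and 2 alone this median was 1.0 and above its random range, and the Fos mean lay above those libraries.

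The medians of the other lists in the authors' deposited table were small. Leukaemia-associated genes had a median of -0.15 against -0.04 to 0.53, with Myc the single called gene of 44 and a median inside its range against libraries 1 and 2 alone (-0.02), and mitochondrial respiratory chain genes -0.29 against -0.16 to 0.40, with 0 of 44 called. Inside the random range were the medians of 31 Polycomb and Trithorax genes (0.40, Cbx8 fell 15.1-fold), 34 imprinted genes (-0.30, 2 higher, namely Peg10 and Plagl1, and 5 lower), 40 interferon-stimulated genes (0.08), 17 stromal and endothelial genes (-0.75), 51 ribosomal protein genes (0.31) and 16 housekeeping genes (0.33) in the authors' deposited table. Peg3, which overlaps Peg3as, fell to 2 reads, a ratio of 28.8 to 859. Cxcl10, within Art3, rose 9.33-fold, Mx1 fell 17.4-fold, Nes rose 7.90-fold, Lepr fell 14.6-fold and Cxcl12 8.97-fold in the authors' deposited table. The wild-type pairs differed for Mx1, at 170 and 68.6 normalised counts against 5.60 in the knockout arm, and for Lepr, at 47.2 and 134 against 4.94. Adjusted over the list alone, the counts were at least 5 and 5 for imprinted, 2 and 2 for stromal, 1 and 1 for interferon-stimulated genes, and 0 and 1 for both Polycomb and leukaemia genes.

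**Figure D3:**
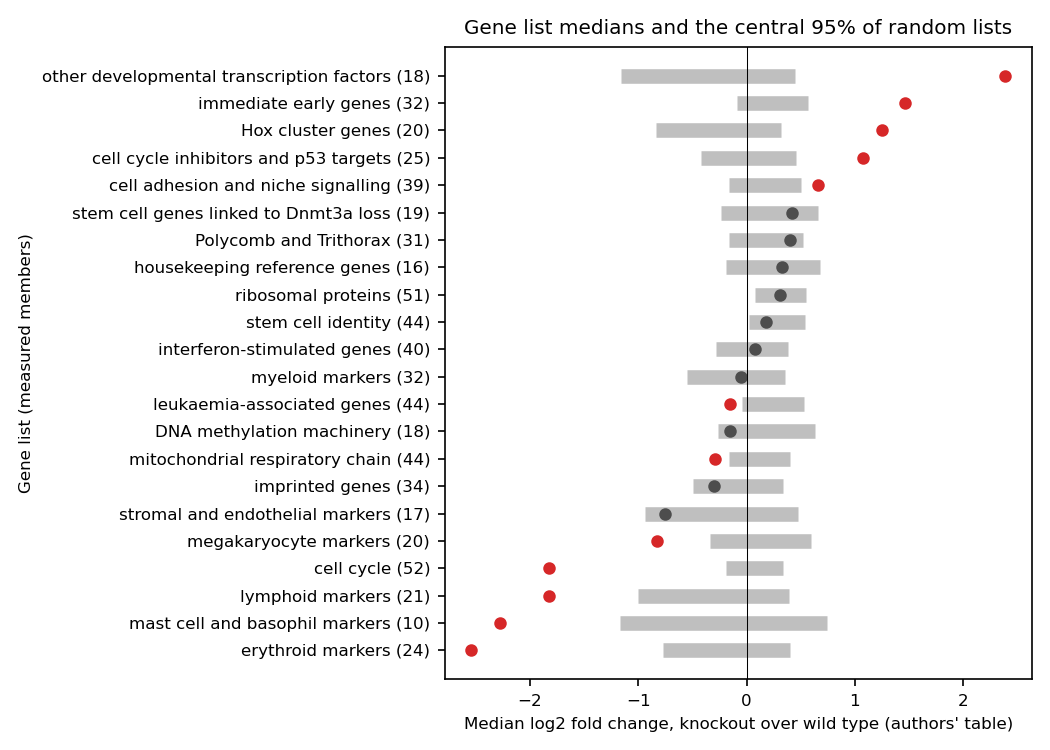
Median log2 fold change of each of the 22 gene lists in the authors' deposited table, with the number of measured members in brackets, over grey bars for the central 95% of 10000 random lists matched on expression. The 5 medians above their bars and the 7 below are red, from 2.39 for developmental transcription factors to -2.54 for erythroid genes.

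These calls rest on the authors' deposited table, whose wild-type side is 1 biological replicate by its labels. Which spread its p-values measure is not known, and no test between genotypes was run here. Of 13161 features with a mean of at least 100, 4130 were at least 2-fold apart in that table. Only 425 of them were called higher and 357 lower, which argues against a spread as small as that within a library pair. The p-values followed the fold rather than each gene's own spread between the wild-type pairs. Klf2, at 51.4 and 4082 in the pairs, had a log2 fold change of -4.13 and an adjusted p of 0.00056 in the authors' deposited table. Jag1, at 187 and 229, had 4.19 and 0.000454 there. For well-counted genes a call is therefore close to a cut on the fold. Scaling by library totals would move each log2 fold change by -0.34 and the median over well-counted features from 0.023 to -0.31, at which the medians of stem cell identity, interferon-stimulated, ribosomal and housekeeping genes turn negative.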

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

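Of 143 values tested over the 4 wild-type libraries, namely totals, shares of counts and the normalised counts of named genes, 0 had a library standing apart from the other 3 beyond Dixon's 95% critical ratio, where chance alone gives about 1 in 20. The measure looks for a lone library, and these libraries split into a pair and a pair. All tests of explanations in this part were chosen after the split was seen.

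The split of libraries 1 and 2 from libraries 3 and 4 was marked in immediate early genes and neutrophil granule genes: 27 of the 32 measured immediate early genes were among the 233 features at least 2-fold higher in libraries 3 and 4. Sequencing lanes of 1 library would differ by counting noise alone, but the lowest median chi-square per degree of freedom across the pairs was 12, which argues against it. A bias by exon length does not account for it either, since 92.1% of the 2-fold features stayed 2-fold after the median difference within 20 length bins was removed. For the granule genes a candidate explanation is that some neutrophils passed the sort, which selects lineage-negative cells, in the sample behind libraries 1 and 2: 19 further neutrophil genes outside the myeloid list had a median log2 difference of -1.34, against -0.25 to 0.28 in random lists, with abundant Chi3l3 at 3641 and 708 and Cd177 at 1129 and 148 normalised counts, but Cxcr2, a receptor of mature neutrophils, was at 159 and 158, Padi4 at 3107 and 3191 and Anxa1 at 4287 and 4833, so mature neutrophils and other sources cannot be told apart. Members of the myeloid and neutrophil lists are only 3.30% of the 636 features lower in libraries 3 and 4, so what separates the rest cannot be told apart, because the lists cover few transcripts and no biological difference between the pairs is labelled.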

How the results depend on the processing

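No paired analysis was possible because the samples form 1 group and the comparison between genotypes comes from the authors' deposited table. At an adjusted p under 0.01, 382 features were higher and 387 lower in that table; with a mean of at least 100, 425 and 357; and among features with gene symbols 525 were lower. At 0.01 the list members called higher dropped from 44 to 28. By list, the numbers called lower dropped from 15 to 7 for cell cycle, 8 to 5 for lymphoid, 4 to 2 for mast cell and 3 to 1 for immediate early genes, and from 1 to 0 for genes linked to Dnmt3a loss, myeloid, inhibitor and leukaemia genes. Those called higher dropped from 9 to 4 for adhesion, 5 to 3 for Hox, 2 to 1 for imprinted and 1 to 0 for stromal genes. These filters keep fewer features by construction. The counts stayed within 1.5 times of the reported ones at an adjusted p under 0.1 (926 and 1117), with a mean of at least 10 (657 and 761), after adjusting again over such features (690 and 809), without overlapping features (531 and 668), and with a 2-fold distance also from libraries 1 and 2 (685 and 801) or from libraries 3 and 4 (685 and 799). A minimum of 2-fold and recentring had no room to change a call, since the smallest called fold is 5.69. The 2-fold distances from a library pair likewise had no room to change a called rise. The symbol, overlap and library-pair alternatives, fold bounds against the lower pair, and those of list medians against each pair or scaled by totals, were chosen after seeing the data.

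Median chi-square per degree of freedom was 7.87 with size factors, 11.6 with at least 100 reads, 4.07 with no minimum, and 7.97 to 8.26 with a replicate left out. It was 0.762 in libraries 1 and 2 alone and 0.681 in libraries 3 and 4 alone. Without the 20 genes with the most counts, the erythroid share was 0.206%, the lymphoid share 0.0329% and the mast cell share 0.2055%; the cause of these shifts is the smaller total. Of 132 list medians recomputed under another setting, 122 kept their side of the random range, including the 22 scaled by totals, which shift every gene alike and had to keep it. Leukaemia-associated genes entered it against libraries 1 and 2 (-0.02) and without matching, as did mitochondrial genes without matching, and the myeloid median left it at -0.59 against libraries 1 and 2 and at 0.50 against libraries 3 and 4. Against libraries 1 and 2, genes linked to Dnmt3a loss (1.0) and the methylation machinery (-0.23) also left it, as did stromal genes without a minimum (-1.28) or without matching and ribosomal genes without matching. The cause was not tested. Low counts limit the genes near silence in 1 arm, for which bounds or intervals are given.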

Other observations

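Genes of this part, and all of its tests, were chosen after their values were seen. The sets were not compared with random lists, so their counts describe these genes alone. Of 13 genes that respond to TGF-beta or bone morphogenetic proteins, 8 were called higher and 0 lower in the authors' deposited table, and Ski, Id2, Tgfb1, Tgfbi and Ltbp1 were not called. The signalling repressor Skil rose 48.7-fold to 126418 normalised counts, thrombospondin Thbs1 48.3-fold and the inhibitor Id3 33.6-fold in the authors' deposited table, while Tgfb1 itself had a log2 fold change of 1.76 and an adjusted p of 0.240. Of 8 measured Notch ligands and targets, 5 were called higher, with the target Hey1 rising 85.1-fold in the authors' deposited table. Of 16 measured targets of the cAMP-responsive factor CREB, 7 were called higher and 1 lower, with Crem rising 71.2-fold, Nfil3 41.1-fold and Ptgs2 23.6-fold in the authors' deposited table. Several of these genes differed between the wild-type pairs: Ptgs2 was at 10.5 and 1365 normalised counts, Hey1 at 4.197 and 37.4, Id3 at 10.5 and 89.0 and Thbs1 at 98.1 and 274, whereas Crem was at 163 and 201. The knockout means were 16290 for Ptgs2, 1903 for Hey1, 1736 for Id3 and 9076 for Thbs1.

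Some markers of tissue macrophages and eosinophils fell. Of 15 macrophage genes, 9 were called lower in the authors' deposited table, including the complement genes C1qc (14.8-fold) and C1qb (11.2-fold) and the regulator Spic (16.9-fold), while 6 others, such as Csf1r and Axl, were not called. Of 7 measured eosinophil genes 6 were called lower, including Ear1 (10.8-fold) and Epx (6.11-fold) in the authors' deposited table. Some of these genes differed between the wild-type pairs: C1qb was at 259 and 70.5 normalised counts in libraries 1 and 2 and libraries 3 and 4, C1qc at 223 and 70.1, Ear1 at 35.7 and 202 and Epx at 234 and 618, whereas Cd163 was at 804 and 648. Loci without a gene symbol by the rule above gave some of the largest differences. HNG_023243 on chromosome 2 (75477252 to 75480727, mm9) went from 33.1 and 99.9 normalised counts to 28728 and overlaps the antisense HNG_021160, with log2 fold changes of 8.73 and 8.86 in the authors' deposited table, while HNG_019567 on chromosome 19 (37309614 to 37312141) went from 966 and 483 to 0 reads. The feature named AK036494, M34473 and abParts on chromosome 6 (70668896 to 70690548) went from 1030 and 2079 to 0.989. Its log2 fold change was -9.44 in the authors' deposited table.

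The fall of erythroid genes was weighed against cells of other kinds in the wild-type sample. Red cells making haemoglobin would bring far more globin than Gata1 transcripts, but the wild-type excess of globin over the knockout arm was 97.6 normalised counts against 1415 for Gata1, a ratio of 0.069. This argues against them only as far as globin reads were counted. The globin genes have near-identical copies, and how reads shared by copies were counted is not given. A larger share of non-stem cells of every kind would lower all lineage markers alike, but the myeloid median was -0.59 against libraries 1 and 2 and 0.50 against libraries 3 and 4, beside -2.80 and -2.69 for erythroid genes. Against the same pairs, tissue macrophage genes had medians of -3.30 and -2.19, and eosinophil genes -2.05 and -3.32. The macrophage and eosinophil sets were chosen after their values were seen, so their falls carry little weight here. The lymphoid and mast cell lists, fixed beforehand, also had negative medians like the erythroid one, at -1.82 and -2.28 in the authors' deposited table. The myeloid list alone therefore cannot decide this. The shares of wild-type counts and of the authors' knockout mean were 0.193% and 0.0714% for erythroid, 0.192% and 0.15% for mast cell, 0.0682% and 0.0420% for stromal, 0.139% and 0.121% for myeloid, 0.394% and 0.370% for megakaryocyte and 0.0308% and 0.0306% for lymphoid markers. The mast cell share includes Kit. In libraries 1 and 2 the megakaryocyte share was 0.338% and 0.337%, below the knockout one, and in libraries 3 and 4 it was 0.444% and 0.441%, above it. The myeloid share was 0.199% and 0.195% in libraries 1 and 2, above the knockout one, and 0.0891% and 0.0906% in libraries 3 and 4, below it. Immature erythroid and megakaryocyte progenitors, which the SP KSL-CD150+ sort is meant to remove, would lower both lists if more passed in the wild-type sample, with the megakaryocyte median at -0.83, and cycling progenitors would also lower cell cycle genes, whose median was -1.82, but lower expression within stem cells of the arm labelled knockout gives the same values, so these cannot be told apart in bulk RNA.

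The rise of immediate early genes in the knockout arm may come from handling before lysis, from genotype or from both. Libraries of the same genotype already differed in these genes by a median of 3.35 on the log2 scale, beside medians of 3.71 for the knockout arm over libraries 1 and 2 and 0.80 over libraries 3 and 4. Handling and genotype cannot be told apart, because the table holds 1 knockout arm. That arm was used only as a mean, without the spread between its libraries. Nr4a3 did not follow the wild-type split, at 7.88 and 7.09 normalised counts against 12622, so a handling effect of the kind seen between the wild-type pairs would have to act on it differently.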
